A study of Sus scrofa with 18 samples.

How the data were processed

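Messenger RNA was measured in 18 libraries of pig tissue, 3 in each of 6 groups formed by genotype (DIK or WT) and tissue label (nose, mouth or scrotum). Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with TRIzol, and libraries were made with the VAHTS mRNA-seq V3 kit. Per the submitters' processing notes, the tools used were fastp, HISAT2 2.1.0 and HTSeq 0.11.2. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so no coordinates are printed. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart. The deposited table holds the authors' count of reads per gene and library as whole numbers, with no normalization.

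The table has 27339 genes, of which 9918 carry placeholder symbols and 501 a suffixed symbol. Of the symbols, 26838 matched a RefSeq table of the assembly Sscrofa11.1, which was used for names only. Each column was assigned to its sample by its name, and groups came from the labels alone. None of the mitochondrially encoded genes was in the table, so 0 genes of that list could be measured. Members of families with near-identical copies, such as actins, keratins, S100 proteins and class I genes, are uncertain because the counting could have split their reads.

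Counts were scaled by TMM and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit), with a mean for each of the 6 groups and all 18 libraries sharing 1 estimate of the spread. Genes were kept by the tool's default filter (minimum count 10, minimum total 15), which left 12895 genes and at least 99.1% of each library's counts. The common biological coefficient of variation was 36.1%. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Contrasts were DIK minus WT at each label, the differences between these contrasts (interactions), and pairs of labels within each genotype. SE was taken as the absolute log2 difference divided by the square root of the F statistic, and log CPM used a prior count of 2. No DIK-WT contrast shared control libraries with another.

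A total of 36 gene lists was fixed before the data were examined, and the 30 with at least 3 tested members were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and also with an estimated correlation. List p-values were adjusted over all lists tested in a contrast. Counts adjusted over the list alone repeat the adjustment among the list's own members. The lists for immune checkpoints, T and NK cells, B and plasma cells, ciliated cells, erythrocytes and mitochondrially encoded genes were too small to test. The fry test, directional and mixed, was an alternative.

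Where a group had 0 counts over its libraries, a fold is given as a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. The intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

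Named genes came from a rule fixed before the data were examined. It takes the RAS-ERK response list, among other items. At each label it takes the 10 largest differences in each direction among called genes with a symbol, at least 10 CPM in the higher group and no overlap of the 3 DIK with the 3 WT libraries, which chance alone gives for 10% of genes. It also takes the 10 genes in each direction with the largest smallest difference over the 3 labels, up to 4 members per list and label by adjusted p, the 5 largest interactions in each direction, and the 5 largest differences in each direction per pair of WT labels with the posterior HOX list. The rule named 289 genes. Which of them the text gives, a set of 131, was chosen after their values and their dependence on the processing had been seen. HRAS and NRAS are outside the rule. Some items are not reported here.

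The steps were tested on simulated data drawn from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold among 12895. At the nose label 4% of 2-fold and 37% of 4-fold changes were called, and 4 of 45 calls were false. At the mouth label these were 4% and 50.0%, with 1 false call of 55, and at the scrotum label 6% and 46%, with 2 false calls of 54. So few changed genes make the adjusted threshold stricter than in the real data, so these shares do not carry over to it.

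Alternatives were other scalings (median-of-ratios, upper-quartile, library size alone), other filters (none, or at least 10 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, only the groups compared, the replicate number as a block, stricter thresholds (adjusted p under 0.01, or at least a 2-fold change), and each library left out in turn. Leaving out WT nose replicate 1 and WT scrotum replicate 2 together was chosen after seeing the data. A move of over 1.5 times without a library was judged on the log2 scale. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 5.95).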

Results

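RNA was sequenced from tumours of a genetically modified pig and from normal tissue of wild-type (WT) pigs. The double knock-in (DIK) line carries the elements of 2 systems for switching genes on, the doxycycline-controlled Tet-on system and the phiC31 integrase. Doxycycline was given to DIK founders and to WT pigs at 7 months of age, and tissue was taken 8 months later. All 9 DIK libraries are from tumours of 1 founder, at sites labelled nose, mouth and scrotum, with 3 libraries per site. The 9 WT libraries are from normal tissue with the same 3 labels. The number of WT animals is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

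The total count per library ran from 418665 (WT nose, replicate 1) to 5041470 (WT nose, replicate 3). The DIK libraries held from 2024959 to 4146150 counts. A floor of 3 counts corresponded to 0.483 to 5.76 CPM (counts scaled to a common library total), so a low value in WT nose replicate 1 carries less weight than in the other libraries. Of the 27339 genes in the table, 12895 had enough counts to be tested. CPM values are given as mean ± SD of 3 libraries, and log2 differences as estimate ± SE from edgeR.

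The genes that mark position along the body were set against the tissue labels. Posterior HOX genes, which are active in the trunk and hind body and silent in the head, were counted in the libraries labelled mouth and hardly in those labelled scrotum. Their summed level was 71.6 ± 16.8 CPM in WT libraries labelled mouth and 6.76 ± 1.14 CPM in those labelled scrotum. In DIK the sums were 19.8 ± 5.68 and 3.34 ± 2.35 CPM. HOXA10 averaged 21.9 ± 6.23 CPM in WT libraries labelled mouth and had 1 count in all those labelled scrotum. The groups are kept here as labelled. Site names and every direction between labels drawn from these libraries rest on labels that these genes go against. If the labels mouth and scrotum were exchanged in both genotypes alike, each DIK-WT difference would keep its libraries and direction under the other site name.

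**Figure D1:**
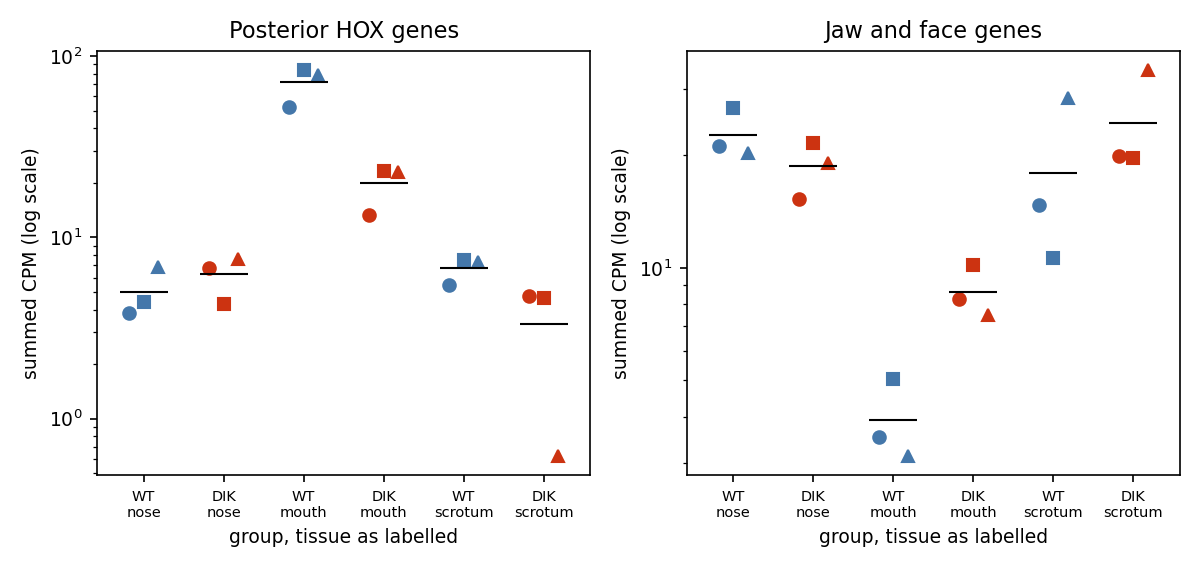
Summed level in CPM of the posterior HOX list and of a list of jaw and face genes in each library, on log axes, by genotype and tissue label, where circles, squares and triangles are replicates 1, 2 and 3, WT is blue, DIK is red and lines are group means. The posterior HOX sums average 71.6 CPM in WT libraries labelled mouth and 6.76 CPM in those labelled scrotum, and the jaw and face sums 3.91 and 17.9 CPM.

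The comparison of DIK tumour with WT tissue asked which genes distinguish the tumours at each site. At the nose label, squamous epithelial and cell-division genes were higher in the tumours, and skeletal muscle genes were lower. With an estimated correlation the oral mucosa and skeletal muscle lists kept their calls and the other lists called there lost them. CRNN, which encodes the cornified envelope protein cornulin, averaged 2708 ± 198 CPM in DIK and 8.50 ± 9.35 CPM in WT, a log2 difference of 8.69 ± 0.99. PYGM, the glycogen phosphorylase of muscle, averaged 2.62 ± 1.78 CPM in DIK and 4385 ± 659 CPM in WT, a difference of -10.69 ± 0.82. AGR2, a protein of mucus-secreting cells, differed by -9.47 ± 0.66. Of the 12895 genes tested, edgeR called 2830 higher and 2596 lower.

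Among the fixed lists at the nose label, all 10 oral mucosa genes rose, also when adjusted over the list alone (camera adjusted p = 1.73e-08, and adjusted p = 0.024 with an estimated correlation). KRT4, a mucosal keratin, averaged 3219 ± 1916 CPM against 25.6 ± 33.0 CPM in WT. SCEL, an envelope precursor with 0 counts in WT, was at least 219-fold higher. Of 22 cornified epidermis genes 21 rose and 1 was not called, again 21 adjusted over the list alone, with a median log2 difference of 7.45 (7.44 with genes at 0 in a group set to their bound). That list had camera adjusted p = 1.99e-06, but adjusted p = 0.389 with an estimated correlation. Its members TGM3, a crosslinking enzyme, and CASP14, a keratinocyte protease, differed by 7.46 ± 1.30 and 9.02 ± 1.79. HRNR, another member, differed by 8.76 ± 2.33, and without WT nose replicate 3 by 7.76, where its edgeR adjusted p was 0.05. Of 14 basal keratinocyte genes 9 rose and 5 were not called, or 12 rose adjusted over the list alone (camera adjusted p = 0.000867; adjusted p = 0.383 with an estimated correlation). TP63, the transcription factor of basal cells, differed by 3.52 ± 0.70, and ITGA6, an integrin, by 2.02 ± 0.57, which fell to 0.98 and was no longer called without DIK nose replicate 2. Of 8 wound and stress keratinocyte genes 7 rose and 1 was not called, in both counts, with a median of 8.76 (camera adjusted p = 8.75e-05; adjusted p = 0.351 with an estimated correlation). GJB2 and GJB6, connexins of gap junctions, differed by 8.48 ± 1.26 and 9.04 ± 1.37, and S100A8, a calprotectin subunit, by 9.90 ± 1.39.

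Of 23 proliferation genes 22 rose and 1 was not called in the nose tumours, also adjusted over the list alone, with a median of 4.70 (4.49 with bounds). This gave camera adjusted p = 2.58e-13, and adjusted p = 0.212 with an estimated correlation. UBE2C averaged 30.8 ± 3.85 CPM against 0.386 ± 0.367 CPM, and PCNA, the replication clamp, differed by 2.24 ± 0.30. TOP2A differed by 5.27 ± 0.73, and by 9.16 without WT nose replicate 3. Of 18 RAS-ERK response genes 8 rose, 3 fell and 7 were not called, the same numbers adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.12). It was called without DIK nose replicate 1 (camera adjusted p = 0.0462) or replicate 3 (camera adjusted p = 0.0395). EPHA2, a receptor kinase, and SPRED1, an inhibitor of the pathway, differed by 1.94 ± 0.36 and 1.96 ± 0.42, while CCND1 and DUSP4 differed by -1.45 ± 0.33 and -1.91 ± 0.36. PHLDA1 was not called at -0.31 ± 0.47, and was called lower at -1.41 without DIK nose replicate 2. Of 8 EGFR ligand genes 5 rose, 1 fell and 2 were not called, in both counts (camera adjusted p = 0.0683). That list was called without DIK nose replicate 1, 2 or 3 (camera adjusted p = 0.0267, 0.0433 and 0.0395), with library size as the only scaling (camera adjusted p = 0.0473), and with a filter of at least 10 CPM in 3 libraries (camera adjusted p = 0.00543). EPGN differed by 4.74 ± 0.54, while BTC, at 0 counts in DIK, was at least 19.3-fold lower. HBEGF differed by 2.73 ± 0.54, and by 1.77 without DIK nose replicate 2.

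Interferon response genes rose in the nose tumours, with 11 of 20 higher and 9 not called in both counts (camera adjusted p = 8.75e-05; adjusted p = 0.351 with an estimated correlation). ISG15, a ubiquitin-like protein, averaged 1122 ± 555 CPM against 20.2 ± 3.98 CPM, OAS1 differed by 2.78 ± 0.38, and OASL, at 0 counts in WT, was at least 186-fold higher. Of 18 antigen presentation genes 5 rose and 13 were not called, in both counts (camera adjusted p = 0.125, and 0.0267 without DIK nose replicate 2). SLA-DRA, a class II chain, differed by 1.69 ± 0.35. Of 16 invasion protease genes 10 rose, 1 fell and 5 were not called, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00953; adjusted p = 0.383 with an estimated correlation). The interstitial collagenase MMP1 differed by 9.83 ± 1.49, and MMP7, with 1 count in DIK and 394 in WT, was lower by a ratio of 570.5 (95% counting interval 101.8 to 22590.0). TIMP1, an inhibitor of these enzymes, differed by 2.15 ± 0.51, and by 1.05 without DIK nose replicate 2. Of 9 inflammatory cytokine genes 7 rose and 2 were not called, in both counts, with a median of 3.28 (3.17 with bounds) and camera adjusted p = 0.0209 (adjusted p = 0.389 with an estimated correlation). The list lost its call without WT nose replicate 2 or 3 or DIK nose replicate 2 (camera adjusted p = 0.0704, 0.0576 and 0.0716), and its median fell to 1.52 without the last. DIK nose replicate 2 stood apart from replicates 1 and 3 in several lists. Summed levels were 4476 CPM against 1253 and 1140.0 CPM for invasion proteases, 425 against 82.1 and 76.7 CPM for inflammatory cytokines, 1128 against 482 and 422 CPM for RAS-ERK response genes, and 1146 against 409 and 452 CPM for EGFR ligands. PTGS2, the inducible prostaglandin synthase, had 491 counts in DIK and 1 in WT, a ratio of 339 (95% counting interval 60.6 to 13420.0); its log2 difference was 8.12, and 5.39 without DIK nose replicate 2.

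Skeletal muscle genes fell at the nose label, 25 of 25 in both counts, with a median of -10.59 (camera adjusted p = 1.22e-42; adjusted p = 0.024 with an estimated correlation). They held 13.3% to 16.3% of all counts in the WT nose libraries and at most 0.1002% in any DIK library. TTN, the giant sarcomere protein, differed by -10.37 ± 0.79 and NEB by -10.59 ± 0.78. Of 14 smooth muscle genes 12 fell and 2 were not called, in both counts (camera adjusted p = 7.87e-07; adjusted p = 0.351 with an estimated correlation), among them MYH11 at -3.88 ± 0.63. Of 11 adipocyte genes 6 fell, 1 rose and 4 were not called, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0204; adjusted p = 0.354 with an estimated correlation), among them LPL at -3.25 ± 0.68. Of 8 Schwann cell and nerve genes 6 fell, 1 rose and 1 was not called, in both counts (camera adjusted p = 0.0205; adjusted p = 0.354 with an estimated correlation), among them S100B at -2.42 ± 0.63. That list was not called with a filter of at least 10 CPM in 3 libraries (camera adjusted p = 0.0637). Among single genes that fell, SAL1, a salivary lipocalin, differed by -13.46 ± 1.65, and WFDC2, at 0 counts in DIK, was at least 501-fold lower. In simulated data for this comparison, 4% of 2-fold and 37% of 4-fold changes were called. Only 100 genes were changed by each fold there, while 42.08% of tested genes were called in the real data. Fewer changed genes make the adjusted threshold stricter, so these shares do not measure what was missed here.

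Several lists at the nose label were not called as a whole. Of 20 fibroblast and matrix genes 8 fell, 2 rose and 10 were not called, in both counts (camera adjusted p = 0.109), with DCN at -3.03 ± 0.48 and COL12A1 at 1.63 ± 0.30. Of 17 hypoxia genes 7 rose, 1 fell and 9 were not called, in both counts (camera adjusted p = 0.258), with SLC2A1, a glucose transporter, at 2.41 ± 0.56 and NDRG1 at 2.63 ± 0.53, or 1.53 without DIK nose replicate 2. The EMT regulators (2 up, 3 down, 9 not called, in both counts; camera adjusted p = 0.65) included VIM at -2.11 ± 0.45 and SNAI2 at 2.74 ± 0.50. Of 11 cell cycle inhibitor and p53 target genes 4 rose, 3 fell and 4 were not called, in both counts (camera adjusted p = 0.191), with CDKN2B at 7.61 ± 1.59. Neutrophil genes rose, 5 of 7 with 2 not called in both counts, with a median of 5.20 (3.54 with bounds; 3.19 without DIK nose replicate 2), camera adjusted p = 0.0229 and adjusted p = 0.354 with an estimated correlation. That call was lost without WT nose replicate 3 (camera adjusted p = 0.0898) and with a filter of at least 10 CPM in 3 libraries (camera adjusted p = 0.0826). The immediate early and heat shock genes, which also respond to tissue handling, rose in 7 of 13 with 6 not called, or 9 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.351 with an estimated correlation). JUNB differed by 3.82 ± 0.54. The macrophage (camera adjusted p = 0.482), mast cell (0.112), endothelial (0.102), melanocyte (0.772), salivary and mucous gland (0.407), cartilage (0.758), hair follicle (0.228), sebaceous gland (0.462) and posterior HOX (0.78) lists were not called.

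**Figure D2:**
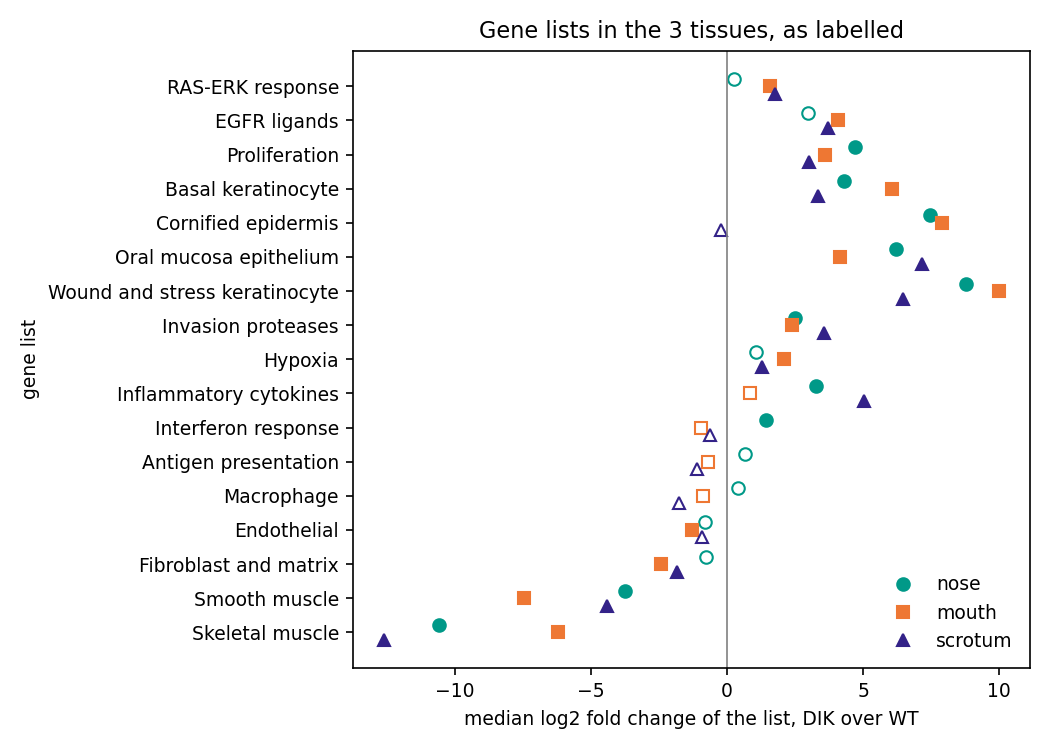
Median log2 difference between DIK and WT of the members of 17 of the fixed gene lists, by tissue label, where filled symbols mark lists with camera adjusted p under 0.05 at the preset correlation of 0.01 and open symbols mark the rest. The proliferation medians are 4.70, 3.61 and 3.02 and the skeletal muscle medians -10.59, -6.23 and -12.60 at the nose, mouth and scrotum labels.

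In the libraries labelled mouth, tumours had higher squamous epithelial, proliferation and hypoxia genes than WT tissue, and lower smooth muscle and connective tissue genes. With an estimated correlation 0 of the 18 lists called here by camera kept their call. The directional fry test called 25 lists, but it does not compare a list with other genes. At this label 46.95% of all tested genes were called. IVL, the envelope protein involucrin, averaged 7723 ± 926 CPM in DIK and 4.44 ± 2.35 CPM in WT, a log2 difference of 10.77 ± 1.88. MYH11, the myosin of smooth muscle, averaged 15.7 ± 5.55 CPM in DIK and 6462 ± 2499 CPM in WT, a difference of -8.68 ± 0.78. DCN, the matrix proteoglycan decorin, differed by -4.70 ± 0.52. edgeR called 2921 genes higher and 3133 lower, and with library size as the only scaling 2118 higher and 3754 lower, which moved the share of higher calls from 48.3% to 36.1%. That scaling shifted the median log2 difference of all genes to -0.29 for this label and -0.21 for the scrotum label, and upper-quartile scaling to -0.15 and -0.17.

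Keratinocyte lists rose in the libraries labelled mouth. Of 14 basal keratinocyte genes 12 rose, 1 fell and 1 was not called, in both counts (camera adjusted p = 3.33e-06; adjusted p = 0.215 with an estimated correlation). CDH3, the placental cadherin, differed by 5.64 ± 0.73 and TP63 by 6.46 ± 0.81. Of 22 cornified epidermis genes 21 rose and 1 was not called, in both counts (camera adjusted p = 2.71e-06; adjusted p = 0.407 with an estimated correlation), among them KLK7, a protease of skin shedding, at 10.48 ± 2.15. Of 10 oral mucosa genes 9 rose and 1 fell, in both counts (camera adjusted p = 3.46e-05; adjusted p = 0.128 with an estimated correlation). KRT4 averaged 217 ± 51.0 CPM against 1.41 ± 0.312 CPM, and RHCG, an ammonia transporter, differed by 8.98 ± 0.80. The wound and stress keratinocyte list had 7 genes higher and 1 lower, in both counts, with a median of 9.99 (camera adjusted p = 2.23e-05; adjusted p = 0.195 with an estimated correlation), and S100A9 differed by 10.03 ± 1.48.

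All 23 proliferation genes rose in the libraries labelled mouth, also adjusted over the list alone (camera adjusted p = 5.05e-17; adjusted p = 0.128 with an estimated correlation). CCNB1, a mitotic cyclin, averaged 25.1 ± 5.79 CPM against 0.336 ± 0.292 CPM. Of 18 RAS-ERK response genes 9 rose, 1 fell and 8 were not called, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00161; adjusted p = 0.253 with an estimated correlation). PHLDA1 differed by 4.42 ± 0.54 and FOSL1, a partner of JUN proteins, by 4.33 ± 0.63. CCND1 was lower by -0.98 ± 0.32 and lost its call without DIK replicate 1 or 2 (-0.93 in each case). Of 8 EGFR ligand genes 6 rose, 1 fell and 1 was not called, in both counts (camera adjusted p = 0.00739; adjusted p = 0.162 with an estimated correlation). AREG, with 320 counts in DIK and 1 in WT, was higher by a ratio of 457 (95% counting interval 81.5 to 18120.0), and HBEGF differed by 3.41 ± 0.55. Of 17 hypoxia genes 12 rose and 5 were not called, or 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.92e-06; adjusted p = 0.151 with an estimated correlation). SLC2A1 averaged 1587 ± 164 CPM against 39.8 ± 25.0 CPM, and EGLN3, an oxygen sensor, differed by 4.71 ± 0.44. Of 16 invasion protease genes 10 rose, 1 fell and 5 were not called, in both counts (camera adjusted p = 0.000252; adjusted p = 0.21 with an estimated correlation), among them PLAU, the urokinase activator of plasmin, at 4.01 ± 0.57. Of 11 cell cycle inhibitor and p53 target genes 5 rose and 6 were not called, in both counts (camera adjusted p = 0.0174; adjusted p = 0.151 with an estimated correlation), with CDKN1A, the p21 inhibitor, at 3.47 ± 0.47. The immediate early and heat shock list had 9 genes higher, 1 lower and 3 not called, in both counts (camera adjusted p = 0.00142; adjusted p = 0.162 with an estimated correlation), with the chaperone HSPA8 at 2.68 ± 0.41.

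All 14 smooth muscle genes fell in the libraries labelled mouth, in both counts, with a median of -7.47 (camera adjusted p = 2.45e-16; adjusted p = 0.128 with an estimated correlation). DES, the muscle filament desmin, differed by -11.44 ± 0.83. Outside the list, MYOCD, a master regulator of smooth muscle genes with 0 counts in DIK, was at least 82.8-fold lower. Of 25 skeletal muscle genes 23 fell and 2 were not called, in both counts, with a median of -6.23 (-4.78 with bounds), camera adjusted p = 4.13e-11 and adjusted p = 0.21 with an estimated correlation. They held 0.198% to 0.522% of counts in the WT libraries of this label. Of 20 fibroblast and matrix genes 17 fell, 1 rose and 2 were not called, in both counts (camera adjusted p = 1.74e-06; adjusted p = 0.21 with an estimated correlation), with COL6A3 at -3.82 ± 0.49 and TNC, an adhesion-modulating matrix protein, at -2.60 ± 0.47. Of 14 EMT regulators 10 fell, 3 rose and 1 was not called, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0166; adjusted p = 0.293 with an estimated correlation), with ZEB2 at -3.65 ± 0.43 and SNAI2 at 2.22 ± 0.48. This call was lost with a filter of at least 10 CPM in 3 libraries (camera adjusted p = 0.0585). Of 14 endothelial genes 9 fell and 5 were not called, in both counts (camera adjusted p = 0.0146; adjusted p = 0.486 with an estimated correlation), with VWF, a clotting protein of vessel walls, at -2.11 ± 0.47. Of 8 Schwann cell and nerve genes 5 fell, 1 rose and 2 were not called, or 6 and 1 adjusted over the list alone, with a median of -3.75 (-3.68 with bounds), camera adjusted p = 0.00947 and adjusted p = 0.215 with an estimated correlation. S100B differed by -4.19 ± 0.67. Of 6 posterior HOX genes 5 fell and 1 was not called, in both counts (camera adjusted p = 0.0178; adjusted p = 0.215 with an estimated correlation), with HOXA10 at -2.68 ± 0.45.

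Immune lists were mostly not called in the libraries labelled mouth. The interferon response list had 2 genes higher, 8 lower and 10 not called, in both counts, with a median of -0.95 (camera adjusted p = 0.141). Against the direction of that median, ISG15 differed by 1.61 ± 0.46. The antigen presentation list had 8 lower and 10 not called, in both counts (camera adjusted p = 0.141), with B2M, the light chain of class I molecules, at -1.82 ± 0.35. The macrophage list had 1 higher, 6 lower and 6 not called, in both counts (camera adjusted p = 0.0738), and was called without WT replicate 2 or DIK replicate 3 (camera adjusted p = 0.0493 and 0.0347); C1QA differed by -1.48 ± 0.37. The inflammatory cytokine list (camera adjusted p = 0.365) had 3 genes higher, 1 lower and 5 not called, with a median of 0.83 (0.32 with bounds). CXCL8, a neutrophil attractant, had 109 counts in DIK and 2 in WT, a ratio of 77.9 (95% counting interval 21.1 to 651), and its call was lost without WT replicate 1, 2 or 3 or DIK replicate 3 (log2 differences of 5.28, 5.36, 8.18 and 4.49). WT replicate 1 of this label stood apart in gland genes: salivary and mucous gland genes held 0.680% of its counts, against 0.0109% and 0.00736% in replicates 2 and 3. The list's median was -1.39 and its mean -1.10 while camera pointed up (adjusted p = 0.682). Without that library the median was 3.66 (camera adjusted p = 0.0274). The secreted gland protein PIP differed by -13.99 ± 2.70, and by -8.15 without it. The keratin KRT8 differed by -4.32 ± 1.31, and its call was lost without WT replicate 1 (-0.60) or without DIK replicate 1 or 2 (-4.07 and -4.04). The neutrophil (camera adjusted p = 0.175), mast cell (0.237), adipocyte (0.209), melanocyte (0.682), cartilage (0.555), hair follicle (0.6) and sebaceous gland (0.494) lists were not called. The hair follicle median was -1.68 (0.00 with bounds) and its mean -0.03, while its test pointed up.

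In the libraries labelled scrotum, tumours had higher mucosal keratin, protease, cytokine and proliferation genes than WT tissue, and lower skeletal muscle and fat genes. With an estimated correlation the protease, cytokine and fat lists lost their calls (camera adjusted p = 0.125, 0.15 and 0.15), while the oral mucosa, proliferation and skeletal muscle lists kept them. LGALS4, the lectin galectin-4, averaged 9521 ± 1153 CPM in DIK and 19.9 ± 25.5 CPM in WT, a log2 difference of 8.89 ± 1.03. The collagenase MMP1 averaged 9416 ± 1693 CPM against 5.27 ± 4.73 CPM, a difference of 10.84 ± 1.46. TTN differed by -12.79 ± 0.87. edgeR called 2507 genes higher and 3100 lower, and with library size as the only scaling the share of higher calls moved from 44.7% to 37.5%.

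WT scrotum replicate 2 stood apart from its group in epidermal genes, so the epidermal lists depend on it. Cornified epidermis genes held 6.35% of its counts, against 0.0128% and 0.00586% in WT replicates 1 and 3 and 1.48% to 1.95% in the DIK libraries of this label. With all libraries 4 of the 22 genes were higher, 5 lower and 13 not called, in both counts, and the median was -0.23 and the mean -0.85 while camera pointed up (adjusted p = 0.0876). Without that library the median was 5.82 (camera adjusted p = 1.28e-09). CASP14 was not called at -1.29 ± 1.23 with it and was higher by 4.43 without it, HRNR went from -9.24 to -0.83 and lost its call, and KLK7 went from 0.31 to 6.50 and gained one. KRT2, an epidermal keratin, went from -10.94 to -1.41 and lost its call. IVL, TGM3 and DSG3 were higher with it (4.97, 5.83 and 5.19) and by more without it (8.95, 9.05 and 8.34). TP63 and PKP1, a desmosome protein, were called only without it (2.73 and 6.59, against 1.42 and 2.53). The same held for CDKN2B (6.45, against 2.72).

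**Figure D3:**
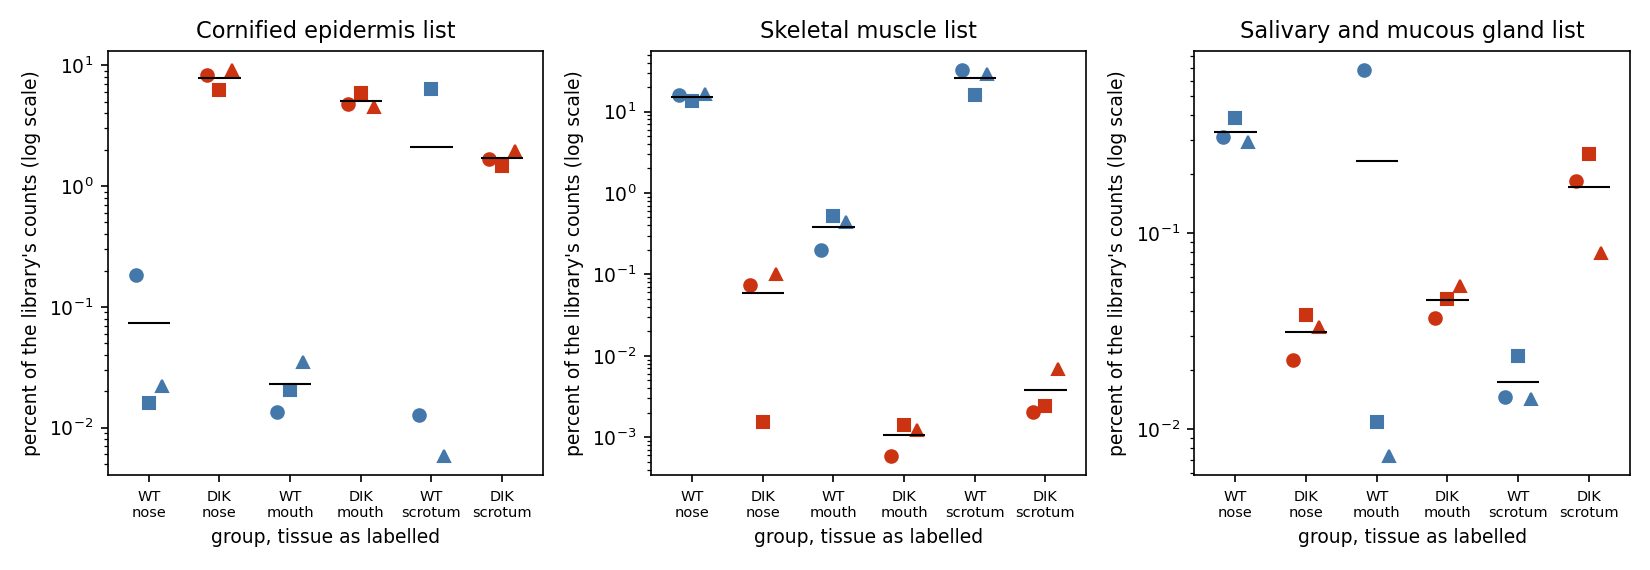
Percent of each library's counts held by marker lists, on a log axis, by genotype and tissue label, where each symbol is a library. Cornified epidermis genes hold 6.35% of counts in WT scrotum replicate 2 but 0.0128% and 0.00586% in replicates 1 and 3, and skeletal muscle genes hold at most 0.1002% in any DIK library.

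Of 10 oral mucosa genes 9 rose and 1 was not called in the libraries labelled scrotum, in both counts, with a median of 7.16 (camera adjusted p = 2.47e-09; adjusted p = 0.0243 with an estimated correlation). MUC21, a membrane mucin, averaged 429 ± 25.2 CPM against 0.487 ± 0.676 CPM, and KRT78 differed by 8.63 ± 1.04. SCEL differed by 5.02 ± 1.07, and by 8.27 without WT replicate 2. Of 14 basal keratinocyte genes 8 rose, 1 fell and 5 were not called, or 9 and 1 adjusted over the list alone (camera adjusted p = 3.22e-05; adjusted p = 0.227 with an estimated correlation), with CDH3 at 4.98 ± 0.71. The median of that list was 3.34, and 6.28 without WT replicate 2. The wound and stress keratinocyte list had 7 genes higher and 1 not called, or 8 higher adjusted over the list alone (camera adjusted p = 2.44e-05; adjusted p = 0.13 with an estimated correlation), with S100A8 at 9.63 ± 1.35. Of 16 invasion protease genes 13 rose and 3 were not called, in both counts (camera adjusted p = 1.81e-07; adjusted p = 0.125 with an estimated correlation). The elastase MMP12 averaged 1843 ± 768 CPM against 0.843 ± 0.527 CPM, and TIMP1 differed by 4.03 ± 0.53. Of 9 inflammatory cytokine genes 8 rose and 1 was not called, in both counts (camera adjusted p = 2.76e-05; adjusted p = 0.15 with an estimated correlation). CXCL8 averaged 267 ± 110.0 CPM against 0.806 ± 0.428 CPM. IL1A, an alarm cytokine of epithelia, differed by 4.97 ± 1.10, and by 8.63 without WT replicate 2.

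All 23 proliferation genes rose in the libraries labelled scrotum, also adjusted over the list alone (camera adjusted p = 6.92e-18; adjusted p = 0.0243 with an estimated correlation), with TOP2A at 2.63 ± 0.50 and PCNA at 2.64 ± 0.29. Of 18 RAS-ERK response genes 11 rose, 2 fell and 5 were not called, or 13 and 2 adjusted over the list alone (camera adjusted p = 2.76e-05; adjusted p = 0.154 with an estimated correlation). EPHA2 averaged 484 ± 74.1 CPM against 36.0 ± 9.39 CPM, EGR1 differed by 3.88 ± 0.59, and DUSP4 was lower by -2.29 ± 0.40. The ERK phosphatase DUSP6 was higher by 1.70 ± 0.56, a call lost without WT replicate 2 or 3 or DIK replicate 1 or 2 (1.54, 1.67, 1.61 and 1.59). CCND1 was higher by 1.05 ± 0.32, lost without WT replicate 1 or 3 or DIK replicate 1 or 2 (0.84, 0.97, 0.91 and 0.92) and with library size as the only scaling (0.90). All 8 EGFR ligand genes were called, 6 higher and 2 lower in both counts (camera adjusted p = 0.00428; adjusted p = 0.0863 with an estimated correlation), with HBEGF at 969 ± 242 CPM against 69.6 ± 20.3 CPM. Of 17 hypoxia genes 8 rose, 1 fell and 8 were not called, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00396; adjusted p = 0.311 with an estimated correlation), with SLC2A1 at 5.30 ± 0.64. The immediate early and heat shock list had 7 genes higher and 6 not called, in both counts (camera adjusted p = 0.000509; adjusted p = 0.125 with an estimated correlation). FOS averaged 370 ± 172 CPM against 1.53 ± 0.701 CPM. Of 7 neutrophil genes 5 rose and 2 were not called, in both counts (camera adjusted p = 0.0163; adjusted p = 0.251 with an estimated correlation), with the chemokine receptor CXCR2 at 2.61 ± 0.51.

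Skeletal muscle genes fell in the libraries labelled scrotum, 25 of 25 in both counts, with a median of -12.60 (camera adjusted p = 4.72e-40; adjusted p = 0.0288 with an estimated correlation), and they held 16.1% to 32.4% of counts in WT. PYGM differed by -13.13 ± 0.92. Outside the list, CKMT2, a creatine kinase of muscle mitochondria with 0 counts in DIK, was at least 5656-fold lower. Of 14 smooth muscle genes 12 fell and 2 were not called, in both counts, with a median of -4.40 (-3.47 with bounds), camera adjusted p = 8.5e-05 and adjusted p = 0.313 with an estimated correlation. Of 11 adipocyte genes 9 fell, 1 rose and 1 was not called, in both counts (camera adjusted p = 8.5e-05; adjusted p = 0.15 with an estimated correlation), with LPL, a lipase, at -5.40 ± 0.75. Of 20 fibroblast and matrix genes 13 fell, 2 rose and 5 were not called, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00814; adjusted p = 0.476 with an estimated correlation), with DCN at -5.51 ± 0.54. Of 8 Schwann cell and nerve genes 6 fell and 2 were not called, or 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0244; adjusted p = 0.313 with an estimated correlation), with S100B at -5.09 ± 0.76. The melanocyte list had 3 of 4 genes lower and 1 not called, in both counts, with a median of -4.21 (-3.12 with bounds), camera adjusted p = 0.0467 and adjusted p = 0.313 with an estimated correlation. That call was lost without WT replicate 1 or 2 (camera adjusted p = 0.0625 and 0.147) and with library size as the only scaling (camera adjusted p = 0.0558). PMEL, a pigment granule protein, differed by -5.54 ± 1.31.

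The antigen presentation list in the libraries labelled scrotum had 9 of 18 genes lower and 9 not called, in both counts (camera adjusted p = 0.051). It was called without WT replicate 1 or 2 or DIK replicate 1 (camera adjusted p = 0.023, 0.0322 and 0.0482), and with median-of-ratios or upper-quartile scaling (camera adjusted p = 0.0476 and 0.0487). The class I gene SLA-1 differed by -1.55 ± 0.36 and B2M by -1.63 ± 0.36, or by -1.03 and -0.98 without WT replicate 3. Of 14 endothelial genes 6 fell and 8 were not called, in both counts (camera adjusted p = 0.0624), and the list was called without WT replicate 2 or DIK replicate 1 (camera adjusted p = 0.0112 and 0.0345). The hair follicle list had a median of -0.46 and a mean of -3.19 while camera pointed up (adjusted p = 0.811). Its genes held 0.1103% and 0.217% of counts in WT replicates 1 and 2 and 0.00102% in replicate 3, and without replicate 3 the median was -5.93 (camera adjusted p = 1.62e-09). The interferon response (camera adjusted p = 0.612), macrophage (0.114), mast cell (0.0963), EMT regulator (0.664), salivary and mucous gland (0.157), cartilage (0.664), sebaceous gland (0.277), p53 target (0.296) and posterior HOX (0.676) lists were not called. Of the 30 lists tested, camera called 14, 18 and 17 at the nose, mouth and scrotum labels, and 2, 0 and 3 of these held with an estimated correlation.

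The tumours were next compared across sites for what they shared. At all 3 labels 1160 genes were higher and 1130 lower in DIK, where independent lists of these sizes would share 124.6 and 151.6. All DIK libraries are from 1 founder and each contrast sets tumour against normal tissue, so more sharing than this was likely beforehand. The shared higher genes included the protease inhibitor A2ML1, with log2 differences of 8.47 ± 0.81, 9.60 ± 0.85 and 10.19 ± 0.85 at the nose, mouth and scrotum labels. ARG1, the enzyme arginase, differed by 9.46 ± 0.91, 8.86 ± 0.86 and 10.88 ± 0.91, and LGALS4 by 9.30 ± 1.08, 9.38 ± 1.08 and 8.89 ± 1.03. The shared lower genes included ACTC1, an actin of striated muscle, at -11.47 ± 1.28, -12.56 ± 1.32 and -11.53 ± 1.29, and CKM, the creatine kinase of muscle, at -9.57 ± 1.42, -10.92 ± 1.53 and -12.27 ± 1.58. Reads of actins, keratins, S100 proteins and class I genes can be split between close relatives in counting, so single members of these families are uncertain. Across genes the fold changes correlated with Pearson's r of 0.746 (nose and mouth), 0.695 (nose and scrotum) and 0.614 (mouth and scrotum), where genes are not independent replicates. Opposite calls were made for 121, 148 and 211 genes in the same order. HRAS and NRAS, chosen after their values were seen, had higher counts in DIK, by 1.51 ± 0.47, 1.83 ± 0.42 and 0.94 ± 0.41 for HRAS and 1.31 ± 0.56, 1.64 ± 0.50 and 2.03 ± 0.53 for NRAS (edgeR adjusted p = 0.0147, 0.00154 and 0.0727, and 0.0684, 0.0112 and 0.00496).

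Whether the tumour difference itself depended on the site was tested with interaction terms. The DIK-WT difference of the interferon response was lower at the mouth label than at the nose label. Its median difference, mouth minus nose, was -2.19, with 9 of 20 genes lower, or 14 adjusted over the list alone (camera adjusted p = 2.4e-11; adjusted p = 0.207 with an estimated correlation). ISG15 differed by -4.17 ± 0.67 and OAS2 by -3.06 ± 0.41 between the 2 labels. The DIK-WT difference was higher at the mouth label than at the nose label for 7 of 17 hypoxia genes, in both counts (camera adjusted p = 2.67e-06; adjusted p = 0.207 with an estimated correlation), among them EGLN3 by 4.42 ± 0.59. EGLN3 was not called at the nose label (0.29 ± 0.40). It was lower in WT libraries labelled mouth than in WT nose by -2.78 ± 0.46, and higher in tumours labelled mouth than in nose tumours by 1.64 ± 0.37. Of 18 antigen presentation genes 7 were lower in the scrotum minus nose difference, or 12 adjusted over the list alone (camera adjusted p = 1.35e-05; adjusted p = 0.55 with an estimated correlation), among them SLA-DRA by -2.11 ± 0.49, or -1.85 and -1.90 and not called without DIK nose replicate 1 or DIK scrotum replicate 2. The DIK-WT difference was higher at the scrotum label than at the mouth label for 4 of 9 inflammatory cytokine genes, in both counts (camera adjusted p = 0.00488; adjusted p = 0.579 with an estimated correlation). The DIK-WT difference of FOS was higher at the scrotum label than at the nose label by 5.51 ± 0.90. At the nose label it was 2.29 ± 0.62, a call lost without DIK nose replicate 2 (1.21) or WT nose replicate 3 (2.00). CCND1, lower in DIK at the nose label and higher at the scrotum label, had an interaction of 2.50 ± 0.46. edgeR called 1109 genes for mouth against nose, 986 for scrotum against nose and 1690 for scrotum against mouth. These counts fell to 657, 433 and 1118 without DIK mouth replicate 2, WT nose replicate 2 and DIK scrotum replicate 2, and the first rose to 1748 without WT mouth replicate 1.

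Normal tissues were compared as a baseline. Between WT libraries labelled mouth and nose 2558 genes differed, between scrotum and nose 780, and between scrotum and mouth 2970. The libraries labelled mouth had more smooth muscle and less skeletal muscle RNA than nose, with MYH11 higher by 4.52 ± 0.64, the calmodulin regulator PCP4 by 4.99 ± 0.53 and TTN lower by -8.45 ± 0.73. AGR2 was lower than in nose by -9.88 ± 0.67 in libraries labelled mouth and by -11.07 ± 0.75 in those labelled scrotum, while PIP was not called between mouth and nose (-0.85 ± 1.46). Salivary and mucous gland genes summed to 2487, 3881 and 3138 CPM in the WT nose libraries and to 5002, 91.3 and 64.0 CPM in replicates 1, 2 and 3 labelled mouth. Between the labels scrotum and mouth, TTN was higher by 9.78 ± 0.77 and MYH11 lower by -6.11 ± 0.69 in libraries labelled scrotum, and TNC lower by -5.68 ± 0.55. The scrotum against nose count was 270 without WT nose replicate 2, 398 without WT nose replicate 3 and 1363 without WT scrotum replicate 2.

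Between tumours edgeR called 199 genes for mouth against nose, 753 for scrotum against nose and 372 for scrotum against mouth, beside 2558, 780 and 2970 between the WT tissues. The difference between these numbers was not tested, and for scrotum against nose their order depended on the setting. With only the groups compared it was 1430.0 genes in DIK and 418 in WT, and with limma-voom 2480.0 and 1352. The median correlation of libraries across genes was 0.966 within and 0.913 between DIK sites, and 0.886 within and 0.738 between WT sites. CRNN was lower by -7.40 ± 0.91 in tumours labelled mouth than in nose tumours, and ISG15 by -3.76 ± 0.50. In tumours labelled scrotum MUC21 was higher than in nose tumours by 5.16 ± 0.50 and than in those labelled mouth by 7.75 ± 0.58. The antimicrobial peptide DEFB1 was higher by 4.59 ± 0.62 and 8.76 ± 0.76 in the same comparisons, and MMP12 by 4.55 ± 0.89 and 5.32 ± 0.92. CASP14 was lower by -6.31 ± 1.48 and -6.34 ± 1.48. The counts of 199, 753 and 372 were lowest at 44, 233 and 176, without DIK mouth replicate 1, DIK nose replicate 1 and DIK mouth replicate 1.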

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

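The test of exchanged labels and the counts over other splits of the samples were fixed before. The posterior HOX pattern was singled out because it goes against the tissue labels. Every other result in this part was singled out because the DIK-WT difference itself differed between 2 labels. The test was an edgeR interaction test, or for a list a camera test. Interaction values are log2 differences of the DIK-WT differences, first label minus second. Such a value can arise in the WT libraries, the DIK libraries or both. Where a group lies near 0 counts, the size depends on the prior count.

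The numbers of genes with such an interaction were 1109 for mouth minus nose, 986 for scrotum minus nose and 1690 for scrotum minus mouth. In 40 splits of the samples, 1 gave as many genes in each case, the real one. The highest other split gave 1075, 586 and 823 genes. The first is close to the real count, which ran from 657 to 1748 with 1 library left out. All DIK libraries are from 1 founder, so these splits do not exclude chance between animals.

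For mouth minus nose, ISG15 (-4.17), OAS1 (-2.86), OAS2 (-3.06) and B2M (-2.14) were lower. CRNN (-4.79), ZEB2 (-2.94), LOX (-3.85), GREM1 (-8.94) and MYOCD (-9.65) were also lower. PHLDA1 (4.74), RHCG (3.21), SLC2A1 (2.90), EGLN3 (4.42), BNIP3 (1.72), CDKN1A (2.65) and AGR2 (12.37) were higher. Several of these sizes lay mainly in the WT tissues. Mouth minus nose was -3.90, -2.98, -9.88, 9.76 and 3.53 in WT for PHLDA1, CDKN1A, AGR2, GREM1 and LOX. In DIK it was 0.84, -0.33, 2.49, 0.82 and -0.32, none called. ISG15, OAS1 and OAS2 differed mainly in DIK, at 0.41, 0.22 and 0.57 in WT and -3.76, -2.64 and -2.49 in DIK. List medians were -2.19 for the interferon response, -1.33 for fibroblast and matrix, -1.14 for macrophage and -3.67 for smooth muscle genes, and 1.48 for basal keratinocyte, 1.03 for hypoxia and 4.76 for skeletal muscle genes. With an estimated correlation none of these lists was called (camera adjusted p of at least 0.207).

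For scrotum minus nose, EPHA2 (1.81), CCND1 (2.50), FOS (5.51) and WFDC2 (13.25) were higher. DCN (-2.48), SLA-DRA (-2.11), SLA-DQB1 (-2.65), C1QA (-2.57), NEB (-3.67) and DES (-3.54) were lower. List medians were 0.91 for the RAS-ERK response, 1.45 for invasion proteases and 3.19 for salivary and mucous gland genes, and -1.78 for antigen presentation and -5.98 for melanocyte genes. These lists too lost their calls with an estimated correlation.

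For scrotum minus mouth, epidermal genes were lower: TP63 by -5.03, PKP1 by -7.09, CASP14 by -11.81, HRNR by -17.01, KLK7 by -10.17, GJB6 by -5.57, KLK6 by -4.60 and KRT2 by -10.31. Most of these sizes rest on WT scrotum replicate 2, whose cornified epidermis genes held 6.35% of counts. Without it CASP14 was -6.11 and HRNR -8.63, still called, while PKP1 (-3.05), KLK7 (-4.00), GJB6 (-2.98) and KRT2 (-0.79) lost their calls and KLK6 turned to 1.44, not called. DUSP4 (-2.11), CXCR2 (-4.33), TTN (-7.52), PYGM (-4.64), PMEL (-9.81) and CKMT2 (-13.52) were also lower. EGR1 (2.67), TIMP1 (2.20), TNC (4.40), CXCL2 (7.28), MYH11 (5.39), DEFB1 (6.45), FAM3B (13.90), GLIPR1 (11.53), IL33 (2.77) and COL12A1 (1.20) were higher. List medians were -8.01 for cornified epidermis (-1.66 without WT scrotum replicate 2), -2.64 for adipocyte and 2.53 for inflammatory cytokine genes. With an estimated correlation no list interaction was called (adjusted p of at least 0.207).

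Many of these interactions lie near the threshold. Of the 12 libraries of each interaction left out in turn, RHCG, BNIP3 and MYOCD (mouth minus nose) and DES (scrotum minus nose) lost their call in 9 cases, SLC2A1 in 7 and CRNN in 3. DCN, NEB and EPHA2 (scrotum minus nose) lost it in 7 and SLA-DRA in 2. For scrotum minus mouth, COL12A1, DEFB1 and KRT2 lost it in 10 cases, PKP1, KLK6 and TIMP1 in 8, EGR1 in 7, GJB6 in 5, the adipocyte list and DUSP4 in 2, and PYGM, KLK7, CKMT2 and FAM3B in 1. Without DIK nose replicate 2 the medians for scrotum minus nose were 1.37 for the RAS-ERK response and 2.99 for invasion proteases, and those for mouth minus nose 2.24 for basal keratinocyte and 1.86 for hypoxia genes. The invasion protease median was 0.87 without WT nose replicate 2, the basal keratinocyte median 2.42 without WT mouth replicate 1, and the hypoxia median 1.63 without WT mouth replicate 3.

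Posterior HOX genes were counted in the libraries labelled mouth and hardly in those labelled scrotum, in both genotypes. If the labels mouth and scrotum had been exchanged in both genotypes, genes of the jaw and face should be higher in the libraries labelled scrotum. Their sum was 17.9 ± 9.29 CPM there and 3.91 ± 1.01 CPM in those labelled mouth in WT, and 24.4 ± 8.08 and 8.63 ± 1.41 CPM in DIK, with no overlap of libraries, log2 ratios of 2.19 and 1.5. An exchange of labels may therefore account for the pattern, while LHX6 went the other way, and neither RNA from another tissue in these libraries nor a biological cause was tested.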

How the results depend on the processing

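Of the counts of genes under the alternatives, 284 stayed within 1.5 times and 59 moved further. Of the single-gene values for the 289 genes named by the rule, 12610 kept their direction and side of the threshold, 423 lost a call, 212 gained one and 11 reversed. Among the 131 genes of the text these numbers were 5902, 120, 36 and 3. Of the list results, 1177 kept, 57 lost and 73 gained a call, and 1 reversed. The estimated correlation accounts for 44 of the lost calls. The directional fry test, which does not compare a list with other genes, called 19, 25 and 24 lists at the nose, mouth and scrotum labels.

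DESeq2 shared 94.9%, 96.3% and 96.8% of the DIK-WT calls at the nose, mouth and scrotum labels.

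Counts that moved with an adjusted p under 0.01 were 1852 genes higher at the nose label, 1623 higher at the scrotum label, 691 higher and 639 lower at all labels, interactions of 390.0, 277 and 733, WT label pairs of 1496, 279 and 1693, and DIK label pairs of 60.0, 266 and 167, in the order mouth against nose, scrotum against nose, scrotum against mouth. With limma-voom the interactions were 3337, 1914 and 2539, the first 2 WT pairs 4399 and 1352, and the DIK pairs 1068, 2480.0 and 1348. With only the groups compared the last 2 WT pairs were 418 and 1557 and the DIK pairs 594, 1430.0 and 1315. DESeq2 gave 323 for DIK mouth against nose. The cause was not tested.

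Leaving out 1 library at a time gave interactions of 657 to 1748, 433 to 1285 and 1118 to 2030 genes, 270 to 1363 for WT scrotum against nose, and 44 to 298, 233 to 866 and 176 to 283 for the DIK pairs. Where a group is left with fewer libraries, the shared spread is assumed to hold for it.

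With limma-voom GSDMA (3.33) and CASP14 (3.30) at the scrotum label and LPO (2.74) and KRT19 (2.98) at the mouth label reversed to higher in DIK. Without WT scrotum replicate 2, CASP14 (4.43), BTG2 (0.94) and LCE1F (2.18) reversed at the scrotum label, and with WT nose replicate 1 also left out they were 4.40, 0.92 and 2.23. KRT19 reversed to 3.84 without WT mouth replicate 1, and the test of the hair follicle list at the scrotum label turned from up to down without WT scrotum replicate 3. Leaving out 1 library at a time gave -1.87 to 4.43 for CASP14, -2.76 to 3.84 for KRT19, -0.86 to 0.94 for BTG2, -1.10 to 3.04 for GSDMA, -1.28 to 3.45 for LPO, -10.53 to 2.18 for LCE1F and medians of -5.93 to -0.05 for the hair follicle list. The cause was not tested.

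The replicate numbers showed no pairing of DIK with WT libraries within a label. There 0 of 9 correlations between same-numbered libraries exceeded 0.1, and 2 of 9 DIK libraries correlated best with their own number. This check did not cover same-numbered libraries across labels within a genotype, so a pairing there is not excluded. With the replicate block the calls higher and lower were 2819 and 2555 at the nose label, 2941 and 3096 at the mouth label and 2526 and 3035 at the scrotum label. The melanocyte list at the scrotum label lost its call with the block (camera adjusted p = 0.0628, with 0.000489 to 0.313 over all its alternatives), and the mast cell list gained one (camera adjusted p = 0.05, with 0.000816 to 0.333).

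With the doubted libraries out, chosen after seeing the data, the calls were 2804 and 2823, 3143 and 3577, and 3173 and 3420. WT nose replicate 1 held 418665 counts, so with its TMM factor of 1.249 a gene with 3 counts there stands at 5.76 CPM. In the simulated data 4%, 4% and 6% of 2-fold changes were called at the nose, mouth and scrotum labels, and depth was not varied apart from the spread and the number of libraries. The simulation changed far fewer genes than were called in the real data, so these shares do not carry over.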

Other observations

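The tests of keratinocyte share against the wound and proliferation values were chosen after the results were seen. The scaling test and the splits of the samples were fixed before.

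Some marker lists had too few tested genes for a test, and their summed levels are given per library. B and plasma cell genes summed to 393.5, 38.8 and 327 CPM in DIK nose replicates 1, 2 and 3, against 17.3, 69.0 and 24.4 CPM in WT nose. In the libraries labelled mouth they summed to 14.4 to 20.3 CPM in DIK and 2.62 to 7.89 CPM in WT, and in those labelled scrotum to 6.79 to 18.1 and 5.71 to 8.81 CPM. Erythrocyte genes summed to 438, 57.9 and 288 CPM in WT scrotum replicates 1, 2 and 3 and to 211, 9.65 and 25.6 CPM in the DIK libraries of that label. T and NK cell genes summed to 16.5 to 51.9 CPM over all libraries, ciliated cell genes to 7.68 to 42.0 CPM, and the immune checkpoint genes to 4.86 to 18.0 CPM.

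The basal keratinocyte and the wound and stress keratinocyte lists were higher and the skeletal and smooth muscle lists lower in the tumours at all 3 labels, by camera with the preset correlation. Of these, only the skeletal muscle list kept its call with an estimated correlation, at the nose and scrotum labels. The cornified epidermis list was higher at the nose and mouth labels, calls lost with an estimated correlation (camera adjusted p = 0.389 and 0.407). At the scrotum label it was not called (median -0.23), and was higher without WT scrotum replicate 2 (5.82). The choice among the scalings run does not account for the basal keratinocyte and skeletal muscle values. Under each of the other scalings the basal keratinocyte median stayed at or above 3.08 and the skeletal muscle median at or below -6.25. These scalings moved the median of all genes no lower than -0.29, so lists this far from 0 could hardly have crossed it. All of them are relative to each library's own counts, so a difference in RNA content was not tested. A higher share of keratinocytes in the tumour pieces stays open as the whole cause for the wound and stress list. Measured against the basal keratinocyte list it was higher in DIK by 3.72, 3.01 and 3.41 at the nose, mouth and scrotum labels (residual SD 0.57; one-sided exact p = 0.000125, the smallest that 8000 assignments can give). The level of basal genes in WT tissue can hide part of a gain in share, and the cornified epidermis list, measured against the basal list in the same way, differed by 3.48, 1.74 and -1.70 (residual SD 1.15; one-sided exact p = 0.0764). Measured against the cornified list the wound and stress list was higher by 0.24, 1.28 and 5.11 (residual SD 1.18), within the spread at the nose label. The one-sided exact p of this measure over the 3 labels together was 0.00238, with the largest part at the scrotum label. For the proliferation list the same measure was -0.36, -2.46 and -1.34 (residual SD 0.75), so a higher keratinocyte share may account for its rise. A change in the keratinocytes themselves stays open as a hypothesis, and tumour and normal tissue were not sampled by cell type.

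In splits of the samples across genotype, 1 of 40 splits, the real one, gave as many genes shared by all 3 labels (1160 higher and 1130 lower), and the highest other split gave 0. Other splits mix tumour and normal libraries within a group, which widens the spread, so few calls were likely beforehand. All DIK libraries are from 1 founder, so the splits do not exclude chance between animals. Each single contrast of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real values at the nose, mouth and scrotum labels were 2830 and 2596, 2921 and 3133, and 2507 and 3100, and the highest other split gave 0 in each case. Between WT labels the real values were 2558, 780 and 2970 and the highest other values 5, 217 and 417. Between DIK labels they were 199, 753 and 372, against 0, 1 and 0.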
